A study of Mus musculus with 14 samples.

How the data were processed

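RNA of 14 mouse mammary samples was hybridised to 1-color oligonucleotide arrays, 1 sample per array, and each of the 3 wild-type samples pooled the RNA of 5 mice per the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, for 12488 probe sets. The software behind these values is not given in the sources used here. In the deposited intensities the mean after trimming 2% from each end was 1500.67 to 1500.9 on every array while the medians differed, so the table was taken as scaled by the authors to a common trimmed mean and was not normalized again.

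Values under a floor of 101 (101.42, the 20th percentile of all values pooled) were set to the floor, and log2 was taken. The 66 control probe sets were left out of the tests, and 3806 others that did not exceed the 40th percentile of their array on at least 3 arrays were removed, which left 8616. Of the values tested, 2.32% were at the floor. Where every array of a group was at the floor, a fold against it is a lower bound, written as at least. Where only some arrays of the lower group and none of the other were at the floor, the fold is also a lower bound. This holds for Krt19, Retn, Vwf and Myh11 in tumors, among others. Such folds are written without at least, and their errors take the floored values as measured. Probe sets were named through the platform annotation supplied with the table: 10855 had 1 gene, 396 had several and were not named, and 1237 had none. The symbols of 10839 were updated by gene number to a current table of mouse gene names (GRCm38.p6), and no coordinates were used. For each of 6397 genes, the probe set with the highest mean log2 value stood for the gene, and no named gene had another probe set called in the opposite direction.

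All 14 arrays entered 1 linear model with 4 groups in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), because groups of 2 to 5 arrays share 1 estimate of the spread this way (10 residual and 5.75 prior degrees of freedom). p-values are two-sided from limma's moderated test, adjusted by the method of Benjamini and Hochberg within each comparison, and a probe set or gene was called at an adjusted p under 0.05. Errors of log2 fold changes are the standard errors of this fit. The number of arrays limits the precision. Data were simulated with the spread of these arrays, 200 of 8616 probe sets changed and no shift between lots. The fit recovered 45% of 2-fold and 94% of 4-fold changes between tumors and wild-type gland. It recovered 44% and 93% between adjacent and wild-type gland, and 61% and 97% between tumors and adjacent gland, with 7, 13 and 5 false calls. Shifts between lots were simulated only for the fit with lot as a fixed block, which recovered 1% and 13%, 1% and 46%, and 13% and 79%. False calls of the fit without a block under such shifts were not simulated. For set B, 15% and 85% were recovered against wild-type gland and 28% and 91% against the first tumors.

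Before the data were examined, 32 gene lists of mammary and other cell types and pathways were fixed, of which 31 had at least 4 measured members; that of mast cells was not tested. They hold 572 measured genes, 8 of them in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation; fry tested whether the members of a list moved, on balance, 1 way. Counts of members called rest on the adjustment over all probe sets tested; those adjusted over the list alone stand beside them. With lot as a block, camera was run in its form for precomputed statistics (cameraPR), on the z-scores of the blocked fit and not on their ranks.

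The genes to name were also set by a rule beforehand. Among genes called with every array of one group above every array of the other, it took the 6 with the largest rise and the 6 with the largest fall in each main comparison. From each list it took up to 4 called members with the largest change, or up to 2 with the smallest p where none was called. It added up to 6 genes per direction called in both adjacent gland and tumors, and the 5 genes with the smallest p where a comparison called none. Not all genes taken by the rule are named. Every gene named as called had all arrays of one group above all arrays of the other, except Egf in tumors against wild-type gland and Socs2, Erbb3, Pcna, H2-Aa and Xist in tumors against adjacent gland.

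The overlap of calls between comparisons that share the wild-type pools was set beside the overlap of independent lists and 100 simulations of unchanged groups against shared controls. In each simulation, the probe sets with the smallest p, as many as were called in the data, stood for the calls. The fit of each comparison has no term for array lot, since lots and groups are confounded in part; lot as a fixed block, lot as a random block and fits within a lot were computed beside it. By the lot numbers as given, no lot holds both tumors and wild-type gland. With lot as a fixed block, their difference is thus a sum. Its parts are that of tumors and adjacent gland in lot 2001815 and that of adjacent and wild-type gland in lot 2004907. The sum takes the adjacent glands of both lots as alike, and among the wild-type pools it rests on pool 40 alone. Where these glands differ, it does not measure the difference of tumors and wild-type gland. Further alternatives were quantile normalization, median scaling, floors at the 5th and 40th percentiles, no filter and a filter at the 60th percentile, no intensity trend, array weights per group, fits of only the groups compared, leaving out each array, and fits with the lots 2004097 and 2004907 taken as one because their numbers differ by exchanged digits. Fits within lots were added after the data were seen. The labels do not say which adjacent gland surrounds which tumor, so no pairs were formed. The probe set of the receptor encoded by the transgene had no name in the annotation and was not analysed here.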

Results

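The series profiled mammary tissue of MMTV-neu mice, in which the promoter of the mouse mammary tumor virus drives the neu oncogene, a form of Erbb2, in mammary epithelium. Each of the 14 arrays measured 1 RNA sample on 12488 oligonucleotide probe sets, and 8616 probe sets passed the filter on dim signals. The samples were 5 mammary tumors, 2 further tumors that the labels set apart as set B, 4 glands taken next to tumors and described as preneoplastic (adjacent gland), and 3 wild-type glands. Each wild-type sample pooled the RNA of 5 mice, pool 40 at 31 weeks and pools 41 and 42 at 41 weeks. The adjacent and wild-type samples are described as steps before tumor formation and their age-matched controls, and set B as a check on whether the changes of the first tumors recur. Nothing in the labels says that each tumor or adjacent gland came from an animal of its own, so p-values measure only the spread between these samples. The receptor encoded by the transgene was not analysed here. The 2%-trimmed mean of each array was close to 1501, the median intensity ran from 544 to 784, and the number of arrays limits the precision.

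The first principal component held 48.0% of the variance and placed the 7 tumors apart from the 7 other arrays. The adjacent glands lay at 23.1 to 43.4 on it, between the wild-type pools at 56.5 to 65.7 and the tumors at -50.3 to -28.9. The second component held 16.2% and was highest for adjacent gland 25 (59.1), followed by tumor 24, both from array lot 2001815. All arrays of this lot lay above 0 on it (14.1 to 59.1), and all arrays of the other lots lay below 0 (-30.2 to -0.239). The arrays came from 5 lots. Lot 2001815 held tumors 22, 24 and 26 with adjacent glands 23 and 25, and lot 2004907 held adjacent glands 49 and 51 with wild-type pool 40. Tumors 50 and 52, wild-type pools 41 and 42, and the set B tumors each had a lot of their own. By these numbers, no lot held tumors together with wild-type gland. The lot of tumors 50 and 52 is numbered 2004097, however. If 2004097 and 2004907 name the same lot, these tumors shared it with pool 40.

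**Figure D1:**
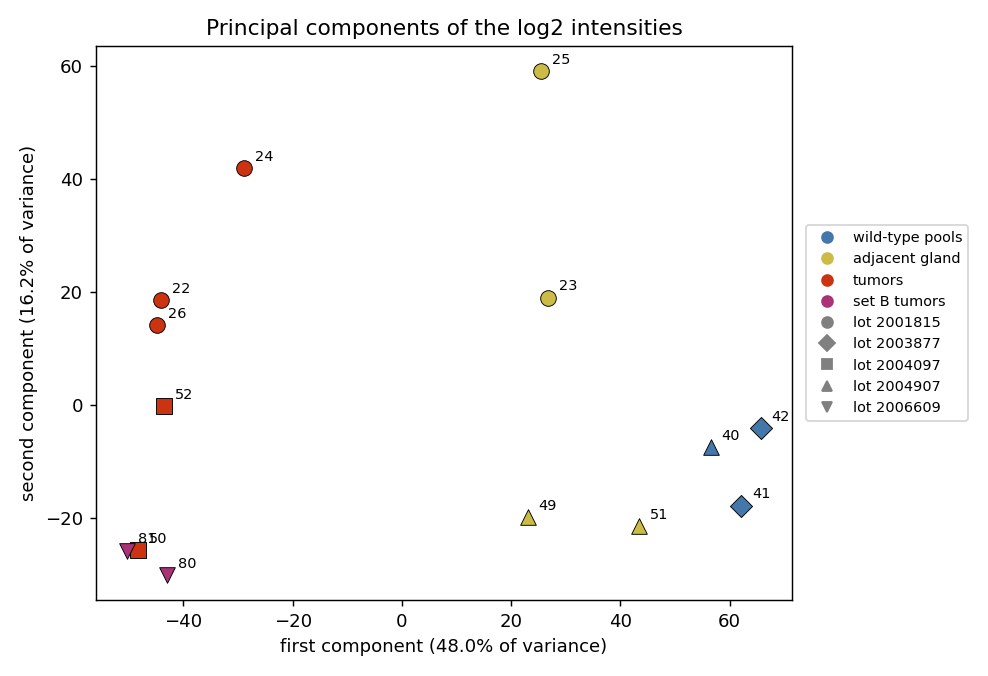
Position of each array on the first (horizontal, 48.0% of variance) and second (vertical, 16.2%) principal component of the log2 intensities, with the number of each sample, its group as color and its array lot as symbol. All 7 tumor arrays lie below 0 on the first component, the wild-type pools at 56.5 or more, and the adjacent glands at 23.1 to 43.4.

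The first comparison asked which transcripts differ between MMTV-neu tumors (n = 5) and wild-type gland (n = 3). Transcripts of fat cells and stroma were far lower in the tumors, and most of those of luminal epithelium were higher. Retn, which encodes the adipocyte hormone resistin, fell by 8.03 ± 0.44 on the log2 scale (SE), from a geometric mean intensity of 35520 to 136. Dcn, which encodes the matrix proteoglycan decorin, fell from 44340 to 2830, by 3.97 ± 0.32. Epcam, an adhesion molecule of epithelial cells, rose from 2003 to 12390, by 2.63 ± 0.26. Dusp6, a phosphatase that acts on ERK kinases, rose from 2311 to 26500, by 3.52 ± 0.40. Adjusted p-values of these 4 genes were 2.96e-09, 2.14e-07, 1.74e-06 and 8.30e-06. With lot as a block in limma, the log2 difference of Retn was at least -7.59, and those of Dcn, Epcam and Dusp6 were -3.29, 1.93 and 4.48. Epcam was not called with the block (adjusted p = 0.0618).

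The largest rises in tumors belonged to genes of several kinds. Npnt, which encodes the integrin ligand nephronectin, was 57.8-fold higher (adjusted p = 1.62e-05), and Npy, which encodes neuropeptide Y, was 43.0-fold higher (adjusted p = 4.14e-05). Scrg1 was at the floor in every wild-type pool and at least 38.1-fold higher in tumors. The secreted carbonic anhydrase gene Car6 was 28.3-fold higher, the ganglioside synthase gene St3gal5 27.9-fold and the fibrillar collagen gene Col11a1 25.7-fold. With array lot as a block, these 6 genes had log2 differences of 3.57 to 5.69, where those of Scrg1 and Car6 are lower bounds. Apart from Retn, the largest falls were those of Ces1d, which encodes a carboxylesterase, at least 242-fold, of the lipid droplet genes Plin4 and Cidec, at least 182-fold and at least 136-fold, of the retinol carrier gene Rbp4, at least 105-fold, and of the amylase gene Amy1, with a log2 change of at least -6.64. These 5 genes were at the floor in every tumor, and with lot as a block their log2 differences were at least -7.38, -6.71, -6.67, -5.62 and -5.43.

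Of 24 measured white adipocyte genes, 22 fell and none rose (22 fell and 1 rose when adjusted over the list alone), with a median log2 change of -4.05. Adipoq, which encodes adiponectin, fell by 6.48 ± 0.40. The list was called by camera (adjusted p = 9.09e-22) and stayed called with an estimated correlation (adjusted p = 0.0151), and its median was -3.23 with lot as a block. Of 7 brown adipocyte genes 5 fell (6 adjusted over the list alone; adjusted p = 0.00182, and adjusted p = 0.324 with an estimated correlation). The uncoupling protein gene Ucp1 fell to the floor in every tumor (log2 change of at least -6.59 ± 1.23). It was also at the floor in the 2 adjacent glands of the lot shared with tumors, so its value with lot as a block says nothing about tumors. The list's median was -2.85, or -0.32 with lot as a block. Of 18 genes of fatty acid and cholesterol synthesis 7 fell and 2 rose (7 and 3 adjusted over the list alone), with adjusted p = 0.036 for the list and adjusted p = 0.431 with an estimated correlation. Among them, the fatty acid synthase gene Fasn fell by 3.42 ± 0.42, the elongase gene Elovl6 by 4.06 ± 0.55 and the lipogenic regulator Thrsp 14.8-fold; with lot as a block their log2 differences were -1.91, -1.98 and -2.58, and none of the 3 was called. The list's median was -0.43, or -0.15 with lot as a block, where its test turned upward without being called.

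Of 34 genes of fibroblasts and extracellular matrix, 25 fell and none rose (26 and 1 adjusted over the list alone), with a median of -1.73. The matrix genes Ogn, Dpt and Clec3b fell by 4.24 ± 0.35, 4.22 ± 0.41 and 3.98 ± 0.32. The list had adjusted p = 1.18e-12, and adjusted p = 0.131 with an estimated correlation; its median was -0.93 with lot as a block. Of 19 endothelial genes 14 fell (15 adjusted over the list alone), among them Vwf, which encodes von Willebrand factor, by 4.79 ± 0.59, and the tight junction gene Cldn5, by 4.20 ± 0.45. The endothelial median was -1.89, or -1.47 with lot as a block, with adjusted p = 1.76e-09 and adjusted p = 0.131 with an estimated correlation. Among 17 basement membrane genes 7 fell and 3 rose (9 and 3 adjusted over the list alone), with Lama2, a laminin chain, 9.37-fold lower; the list had adjusted p = 0.0196, and adjusted p = 0.376 with an estimated correlation. Of 18 matrix proteases and inhibitors 6 fell (6 fell and 1 rose adjusted over the list alone), with the stromelysin gene Mmp3 down by 3.99 ± 0.66; adjusted p was 0.0163, and adjusted p = 0.324 with an estimated correlation. With lot as a block, the basement membrane and protease medians went from -0.77 and -0.49 to -0.37 and -0.20. White adipocyte genes fell in the same arrays, as did 17 of 24 skeletal muscle genes, while 1 rose (median -3.06, or -5.91 with lot as a block; adjusted p = 7.33e-08, and adjusted p = 0.324 with an estimated correlation). The count of muscle genes was the same adjusted over the list alone. The muscle actin gene Acta1 fell by 6.42 ± 1.49.

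Of 24 measured luminal epithelial genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.22. The transcription factor gene Ehf rose by 2.61 ± 0.32 and the protease inhibitor gene Spint1 by 2.38 ± 0.24. The list had adjusted p = 4.44e-07, and adjusted p = 0.131 with an estimated correlation, and its median was 0.99 with lot as a block. The member that fell was Krt19, a keratin of simple epithelia, which went from 11120 to 202 (log2 change -5.78 ± 0.64, adjusted p = 5.95e-06, and -4.54 with lot as a block). It was at the floor in tumors 26, 50 and 52, so this fall is a lower bound. Of 7 hormone-sensing luminal genes 3 fell and 1 rose, over all genes and adjusted over the list alone. The pioneer transcription factor gene Foxa1 fell by 4.29 ± 0.37, the transcriptional co-regulator gene Cited1 by 3.03 ± 0.39 and the Wnt ligand gene Wnt4 by at least 2.26 ± 0.58, while Socs2, an inhibitor of cytokine receptor signaling, rose by 3.90 ± 0.49. This list of mixed directions was not called (adjusted p = 0.133). Log2 differences of Foxa1, Cited1 and Socs2 were -5.90, -3.92 and 4.68 with lot as a block. Of 15 basal and myoepithelial genes 9 fell and 2 rose (9 and 3 adjusted over the list alone), with the smooth muscle genes Myh11 and Cnn1 down by 5.42 ± 0.44 and 3.93 ± 0.33. The basal median was -1.53, or -1.63 with lot as a block, with adjusted p = 0.00155 and adjusted p = 0.131 with an estimated correlation. Of 16 genes of milk proteins and secretion 6 rose and 1 fell, also when adjusted over the list alone. Among them Xdh, which encodes an enzyme of the milk fat globule, rose by 3.78 ± 0.60. The milk list was not called (median 0.09, adjusted p = 0.358, and adjusted p = 0.762 with an estimated correlation). At the preset correlation with lot as a block its median was 1.54 and it was called. With the block, however, the milk median was 1.65 in adjacent against wild-type gland and -0.27 in tumors against adjacent gland. The blocked value for tumors takes the adjacent glands of both lots as alike. By itself it therefore does not show a rise of milk genes in tumors.

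**Figure D2:**
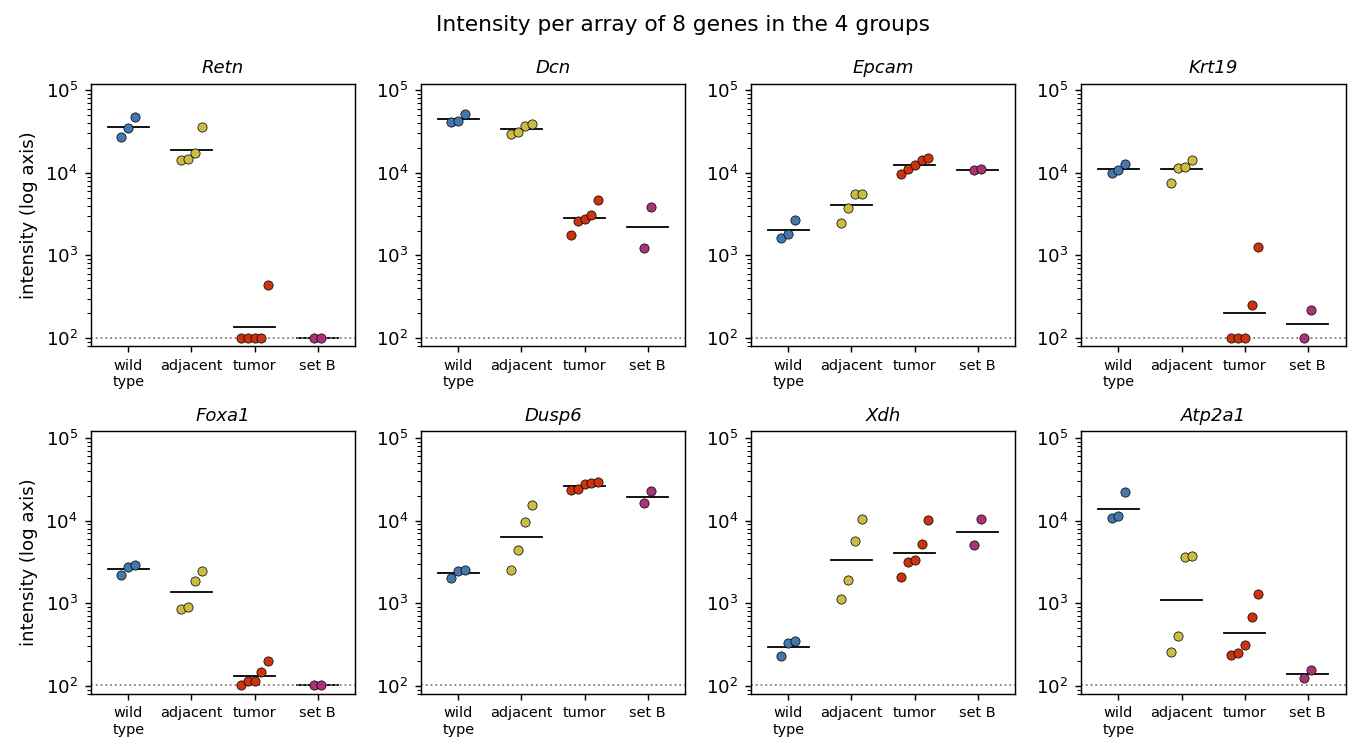
Intensity of 8 genes on a log axis in each array of the wild-type (n = 3), adjacent (n = 4), tumor (n = 5) and set B (n = 2) groups, with points for arrays, a bar for the geometric mean and a dotted line at the floor of 101. Epcam was higher in every tumor than in every wild-type pool, while Krt19 stood at 11120 in wild-type and 10970 in adjacent gland, and at 202 in tumors.

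Of 16 genes of ErbB receptors, ligands and adaptors 10 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 1.49. Besides Dusp6, the ligand genes Egf and Tgfa rose by 2.65 ± 0.78 and 2.49 ± 0.45, and Errfi1, a feedback inhibitor of these receptors, by 2.08 ± 0.22. The list had adjusted p = 0.00756, and adjusted p = 0.324 with an estimated correlation; its median was 0.67 and Egf's log2 difference 0.97 with lot as a block. Of 43 cell cycle genes 15 rose and none fell (18 adjusted over the list alone). Rrm2, a subunit of ribonucleotide reductase, rose by 1.74 ± 0.33, the mitotic kinase gene Ttk by 1.21 ± 0.31 and the mitotic kinesin gene Kif20a by 1.19 ± 0.32. The list had adjusted p = 3.01e-05, and adjusted p = 0.431 with an estimated correlation. Its median was 0.74, but 0.01 with lot as a block, where Rrm2 differed by 0.65 and Ttk by -0.10. Of 32 oxidative phosphorylation genes 16 fell and 1 rose (18 and 1 adjusted over the list alone), with the succinate dehydrogenase subunit gene Sdha down by 1.92 ± 0.27. This median was -0.57, or -0.04 with lot as a block, with adjusted p = 5.95e-06 and adjusted p = 0.324 with an estimated correlation. Of 22 genes of protein folding and endoplasmic reticulum stress 7 rose, also when adjusted over the list alone, with the disulfide isomerase gene Pdia3 up by 2.03 ± 0.26 and the transcription factor gene Xbp1 up by 1.45 ± 0.18; adjusted p was 0.0142, and adjusted p = 0.324 with an estimated correlation. Of 21 interferon response genes 10 rose and 2 fell (10 and 3 adjusted over the list alone), with Ifit1 and Usp18, which are induced by interferon, up by 3.13 ± 0.52 and 2.71 ± 0.65. The interferon list had adjusted p = 0.0283, and adjusted p = 0.582 with an estimated correlation. The folding and interferon medians of 0.45 and 0.72 were 0.28 and 1.04 with lot as a block.

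limma called 2574 of 8616 probe sets, 1359 higher and 1215 lower in tumors, of which 1742 changed at least 2-fold; the calls covered 1956 genes. camera called 15 of 31 lists at the preset correlation, and only the white adipocyte list with an estimated one; fry called 19. With lot as a block 360 probe sets were called, of the 123 named genes called here 121 kept their direction and 43 their call, and 7 of the 15 lists lost theirs: cell cycle, oxidative phosphorylation, ErbB, brown adipocyte, lipid synthesis, basement membrane and proteases. Genes named above that lost the call with the block were Npnt, Npy, Scrg1, Col11a1, Amy1, Krt19, Epcam, Wnt4, Ucp1, Elovl6, Thrsp, Fasn, Rrm2, Ttk, Kif20a, Egf, Tgfa, Errfi1, Lama2, Mmp3, Vwf, Cldn5 and Sdha. The 3' to 5' ratio of the actin control was 0.08 to 0.76 (log2) in the 5 tumors, below each wild-type pool (0.90 to 1.51), so RNA integrity and group are not separated in this comparison; that of Gapdh was -0.25 to 0.43 against 0.11 to 1.48. When each array was left out in turn, 102 of the 123 kept the call every time; Wnt4, Egf, Ttk and Kif20a were among those that lost it, and the lists of interferon response and of fatty acid and cholesterol synthesis also lost theirs.

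The second comparison asked which transcripts differ between adjacent gland (n = 4) and wild-type gland (n = 3). Few single genes were called, and the lists called at the preset correlation, among them milk and luminal genes upward and skeletal muscle and fat downward, were not called with an estimated one. Xdh rose from 297 to 3350, by 3.49 ± 0.63 on the log2 scale (adjusted p = 0.0153; 4.56 within lot 2004907). Acsl4, which encodes a ligase that activates arachidonic acid, rose from 1046 to 6175, by 2.56 ± 0.28 (adjusted p = 0.001; 2.34 within the lot). Atp2a1, the calcium pump of fast skeletal muscle, fell from 13830 to 1089, by 3.67 ± 0.83 (adjusted p = 0.0449; -6.09 within the lot); it stood at 3748 and 3603 in glands 23 and 25 of one lot and at 258 and 404 in glands 49 and 51 of another. Krt19 stood at 10970 in adjacent and 11120 in wild-type gland.

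Further rises included Car6, 8.36-fold, the B cell transcription factor gene Pax5, 5.31-fold, the signaling adaptor gene Dok1, 5.30-fold, the cartilage collagen gene Col9a1, 5.01-fold, and the carbonic anhydrase gene Car12, 4.89-fold. Further falls were those of the muscle phosphoglycerate mutase gene Pgam2, 6.05-fold, of Ryr1, the calcium release channel of skeletal muscle, 4.44-fold, of the galactosyltransferase gene B3galt2, 4.10-fold, of the muscle enolase gene Eno3, 3.80-fold, and of the plasma glutathione peroxidase gene Gpx3, 3.78-fold. Within lot 2004907, the log2 differences of these 5 risers were at least 3.49 (Car6), 2.28, at least 3.71 (Dok1), 2.20 and 2.62, and those of the 5 fallers were at least -4.27 (Pgam2), -3.38, -1.81, -3.36 and -1.84.

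Of 24 luminal epithelial genes 2 rose and none fell, or 9 and none adjusted over the list alone. They were Ehf, up by 1.49 ± 0.33, and the tight junction gene Cldn7, up by 1.23 ± 0.23, with log2 differences of 1.33 and 1.76 within lot 2004907. The list's median was 0.66, or 0.50 within the lot, with adjusted p = 9.53e-08 and adjusted p = 0.207 with an estimated correlation. Of 16 genes of milk proteins and secretion 3 rose, also when adjusted over the list alone: Xdh, the folate receptor gene Folr1 by 1.42 ± 0.33 and the kappa-casein gene Csn3 by 1.30 ± 0.28. The milk median was 1.02, or 1.65 within the lot, with adjusted p = 8.47e-04 and adjusted p = 0.549 with an estimated correlation. Of 24 white adipocyte genes 2 fell, or 9 adjusted over the list alone. The adipogenic transcription factor gene Cebpa fell by 1.37 ± 0.30 and Cidec by 1.25 ± 0.28, against log2 differences of -0.96 and -0.98 within the lot. The adipocyte median was -0.89, or -0.62 within the lot, with adjusted p = 3.63e-10 and adjusted p = 0.207 with an estimated correlation. Of 24 skeletal muscle genes 3 fell, or 17 fell and 1 rose adjusted over the list alone, with a median of -1.98 and one of -3.70 within the lot; adjusted p was 2.05e-11, and adjusted p = 0.549 with an estimated correlation. Acta1, which was not called here, stood at 17370 and 15560 in glands 23 and 25, at 173 and 170 in glands 49 and 51 and at 22100 to 41070 in the pools.

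The lists of cell cycle, ErbB, endothelium, oxidative phosphorylation and fatty acid and cholesterol synthesis were called without any member called alone. Adjusted over the list alone, 1 ErbB gene rose, 2 endothelial genes fell and no member of the other 3 lists changed. The cell cycle median was 0.36 (adjusted p = 0.00277, and adjusted p = 0.757 with an estimated correlation) and the ErbB median 0.65 (adjusted p = 0.0134, and adjusted p = 0.549 with an estimated correlation). The endothelial median was -0.37 (adjusted p = 0.0172, and adjusted p = 0.661 with an estimated correlation). The median of oxidative phosphorylation was -0.49 (adjusted p = 1.21e-07) and that of lipid synthesis -0.46 (adjusted p = 0.00898), both with adjusted p = 0.549 with an estimated correlation. Within lot 2004907 these 5 medians were -0.09, 0.14, -0.20, -0.12 and -0.07. Among the ErbB genes, Dusp6 stood at 6401 in adjacent and 2311 in wild-type gland, a log2 difference of 1.47 ± 0.42 that was not called (adjusted p = 0.1). Single genes called in lists that were not called included the transcriptional inhibitor gene Id2, up by 1.33 ± 0.24, and the apoptosis effector gene Bak1, up by 1.41 ± 0.26.

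limma called 101 of 8616 probe sets, 62 higher and 39 lower in adjacent gland, of 80 genes; camera called 9 of 31 lists, none of them with an estimated correlation, and fry called 2, luminal epithelium and white adipocyte. The count was 56 with lot as a block, where the luminal, milk, white adipocyte and skeletal muscle lists kept their calls and the other 5 lost them, and 0 within lot 2004907 (523 at an unadjusted p under 0.05), where 1 pool stood against 2 glands and all 22 named genes called here kept their direction; it was 50, 24 and 14 without wild-type pool 40, 41 and 42, and 36 and 200 without adjacent gland 49 and 51. The direction of these 22 within the lot was fixed in advance, since each had all arrays of one group above all arrays of the other. The block gave the same log2 differences as the fit within the lot. With the block, 9 of the 22 kept their call. Car6, Pax5, Col9a1, Car12, B3galt2, Gpx3, Ehf, Folr1, Csn3, Cebpa, Cidec and Id2 were among those that lost it. Of the 22 genes only Acsl4 kept its call each time an array was left out, and of the 9 lists the luminal, white adipocyte, skeletal muscle and oxidative phosphorylation lists did. The ratio of 3' to 5' signal of the Gapdh control, a measure of RNA integrity, was -0.27 to 0.27 (log2) in adjacent gland and 0.11 to 1.48 in the wild-type pools.

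**Figure D3:**
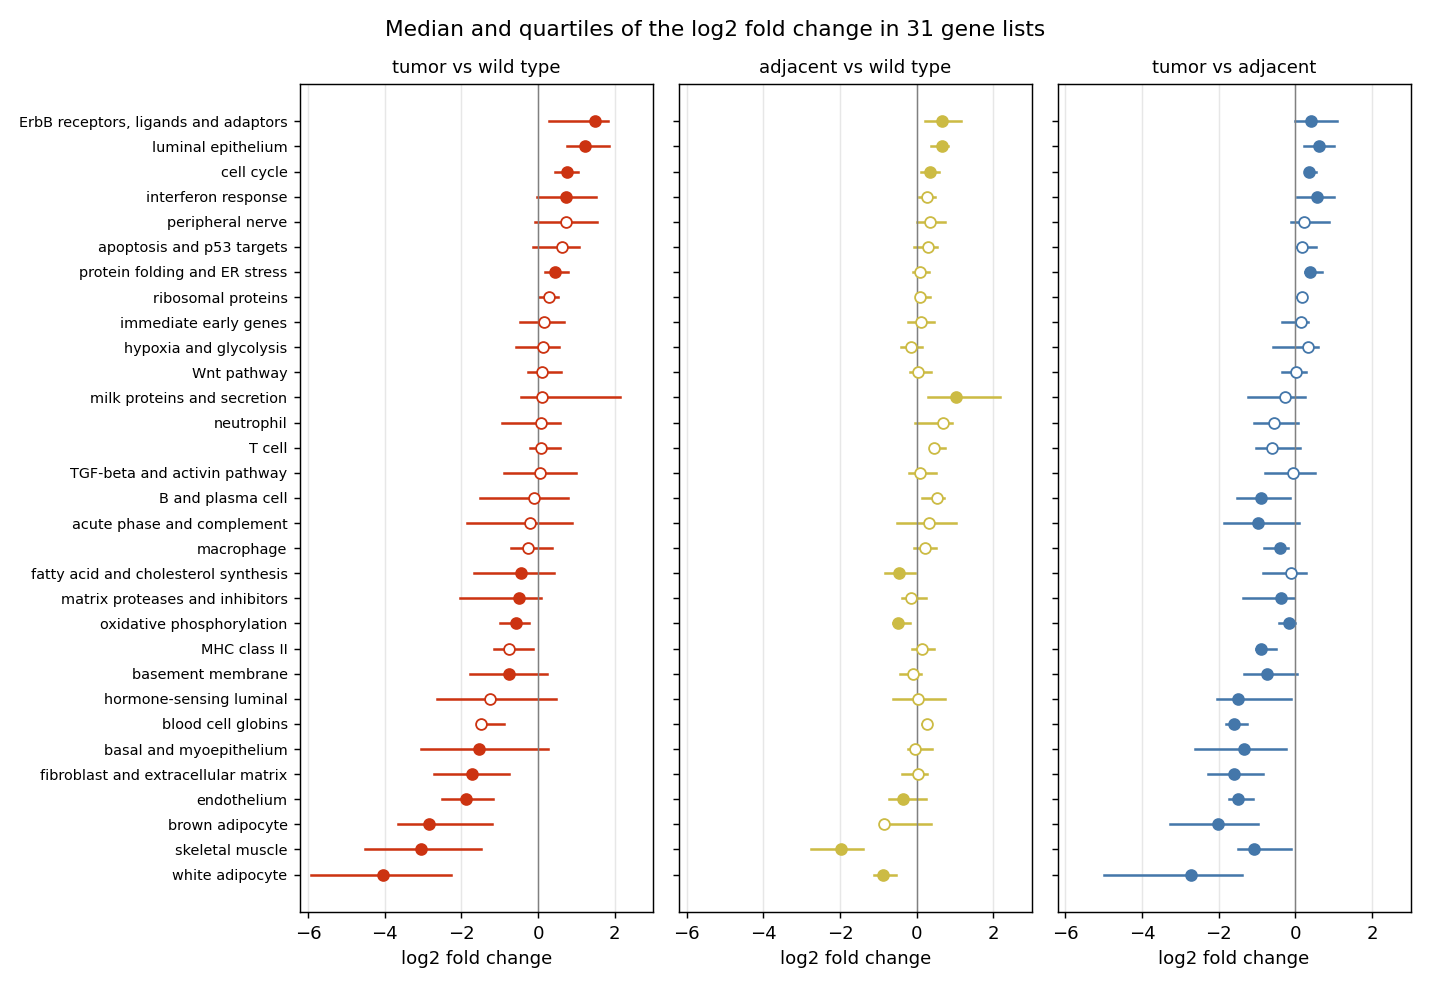
Median (point) and quartiles (line) of the log2 fold change of the measured members of 31 gene lists in 3 comparisons, with filled points where camera called the list at its preset correlation. White adipocyte genes had the lowest medians in tumors against wild-type gland (-4.05) and in tumors against adjacent gland (-2.73), and luminal epithelial genes had medians of 1.22, 0.66 and 0.62 in the 3 comparisons.

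The third comparison set the tumors (n = 5) against the transgenic gland next to tumors (n = 4). Fat and stromal genes were far lower in tumors, and most basal and myoepithelial genes fell. Retn was 139-fold lower and Car3, the carbonic anhydrase of fat and muscle, 63.2-fold lower (adjusted p = 6.44e-09 and 3.27e-09). Krt19 fell by 5.76 ± 0.58 on the log2 scale (adjusted p = 4.51e-06). Among the rises, Npy was 8.93-fold higher, Ifit1 7.03-fold and Ier3, an immediate early gene, 5.51-fold (adjusted p = 0.00413, 6.81e-04 and 3.72e-04). Within lot 2001815, which held 3 of the tumors and 2 of the glands, the log2 differences of these 6 genes were at least -7.30 (Retn), -5.64, -4.89, 2.80, 3.84 and 2.40.

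The heparan sulfate sulfotransferase gene Hs3st1 was 6.90-fold higher, Car8 5.90-fold and the protease inhibitor gene A2m 5.36-fold, while Ces1d, Plin4 and Cidec were at least 78.3-fold, at least 62.2-fold and at least 57.1-fold lower. Within the lot, these 6 genes had log2 differences of 3.18, 2.80, 1.73, at least -6.03, at least -5.62 and at least -5.69.

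Of 24 white adipocyte genes 21 fell (22 adjusted over the list alone; median -2.73, or -2.39 within lot 2001815), of 34 fibroblast and matrix genes 27 fell (28; median -1.61, or -1.23), of 19 endothelial genes 15 fell (16; median -1.49, or -1.17) and of 15 basal and myoepithelial genes 9 fell and 1 rose (9 and 2; median -1.35, or -1.32). These 4 lists were called (adjusted p = 8.48e-27, 1.46e-20, 1.60e-12 and 1.53e-06) and stayed called with an estimated correlation (adjusted p = 0.00676, 0.0443, 0.0443 and 0.0381). The proteoglycan genes Dcn and Lum fell by 3.58 ± 0.29 and 3.51 ± 0.40, Cldn5 by 3.77 ± 0.41 and Myh11 by 4.57 ± 0.40. Of 7 hormone-sensing luminal genes 2 fell and 1 rose (4 and 1 adjusted over the list alone): Foxa1 fell by 3.37 ± 0.34 and Cited1 by 2.55 ± 0.36, and Socs2 rose by 2.34 ± 0.45, with log2 differences of -4.26, -2.76 and 2.66 within the lot. That list had adjusted p = 0.0271, and adjusted p = 0.19 with an estimated correlation. Of 24 luminal genes 11 rose and 1 fell (14 and 1 adjusted over the list alone), Epcam by 1.60 ± 0.24 and Spint1 by 1.41 ± 0.22, with adjusted p = 2.12e-04 and adjusted p = 0.19 with an estimated correlation. The hormone-sensing median was -1.50, or -1.55 within the lot, and the luminal median 0.62, or 0.63.

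Of 16 ErbB genes 4 rose (4 rose and 1 fell adjusted over the list alone), among them Dusp6 by 2.05 ± 0.37, Tgfa by 1.75 ± 0.41 and the receptor gene Erbb3 by 0.88 ± 0.27; the list's median was 0.40, or 0.19 within the lot, with adjusted p = 0.0238 and adjusted p = 0.402 with an estimated correlation. Of 22 folding genes 6 rose, also when adjusted over the list alone, among them Xbp1 by 0.88 ± 0.16 (list median 0.37, or 0.55 within the lot; adjusted p = 0.00203, and adjusted p = 0.148 with an estimated correlation). Of 21 interferon genes 4 rose and 2 fell (6 and 3 adjusted over the list alone; median 0.57, or 0.68 within the lot; adjusted p = 0.0199, and adjusted p = 0.553 with an estimated correlation). Of 43 cell cycle genes 1 rose, Pcna, the polymerase clamp, by 0.73 ± 0.23, and none did adjusted over the list alone; the median was 0.36, or 0.09 within the lot, with adjusted p = 9.51e-04 and adjusted p = 0.526 with an estimated correlation. Of 12 B and plasma cell genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), with the immunoglobulin genes Igha and Jchain down by 3.38 ± 0.37 and 3.18 ± 0.32; the list's median was -0.91, or -0.39 within the lot, with adjusted p = 0.00954 and adjusted p = 0.352 with an estimated correlation. Of 9 genes of MHC class II 3 fell (4 adjusted over the list alone), with H2-Aa down by 1.43 ± 0.44; the median was -0.89, or -0.84 within the lot, with adjusted p = 0.0182 and adjusted p = 0.33 with an estimated correlation. Of 24 macrophage genes 4 fell, also when adjusted over the list alone, with the mannose receptor gene Mrc1 down by 1.98 ± 0.34; the median was -0.39, or -0.10 within the lot, with adjusted p = 0.0145 and adjusted p = 0.473 with an estimated correlation. In the same arrays 2 of 24 skeletal muscle genes fell, also when adjusted over the list alone, with a median of -1.09, or -2.13 within the lot (adjusted p = 0.00764, and adjusted p = 0.555 with an estimated correlation). Here glands 23 and 25 stood apart from glands 49 and 51, whose Acta1 signal of 173 and 170 lay within the range of the tumors (101 to 2296).

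limma called 1239 of 8616 probe sets, 460 higher and 779 lower in tumors, of 962 genes; camera called 20 of 31 lists, 5 upward and 15 downward, and fry called 16. With lot as a block 597 probe sets were called, and 209 within lot 2001815. Both gave the same log2 differences, and all 104 named genes called here kept their direction, with 64 and 29 keeping their call. For genes with all arrays of one group above all arrays of the other, the direction was fixed in advance. With the block 10 of the 20 lists lost their call, among them ErbB, cell cycle, B and plasma cell, MHC class II and macrophage. Npy, A2m, Tgfa, Erbb3, Pcna, H2-Aa and Mrc1 were among the genes not called with the block. When each array was left out in turn, 84 of the 104 genes and 11 of the 20 lists kept the call every time; Pcna, Erbb3 and H2-Aa and the hormone-sensing, ErbB, interferon, cell cycle, B and plasma cell, MHC class II, macrophage, skeletal muscle and oxidative phosphorylation lists lost it.

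The overlap of both comparisons with wild-type gland was then counted. All 101 probe sets called in adjacent gland were called in the same direction in tumors against wild-type gland, 62 higher and 39 lower, among them Xdh, Car6, Acsl4, Dok1, Col9a1 and Car12 upward and Atp2a1, Pgam2, Ryr1, B3galt2, Eno3 and Gpx3 downward. Independent lists of these sizes would share 9.78 higher and 5.5 lower. Among the falls named here, those of Atp2a1, Pgam2, Ryr1 and Eno3 belong to skeletal muscle genes. Whether they follow the amount of muscle in each sample was not tested. Both comparisons used the same 3 wild-type pools. In 100 draws of groups without any change, the 101 and 2574 probe sets with the smallest p shared a mean of 81.1 in the same direction, at most 91. These simulated lists were chosen on noise alone, so 81.1 is not the overlap expected from shared controls in these data. The log2 fold changes correlated across probe sets, which are not independent replicates, with r = 0.75, against 0.599 in the simulation, and their covariance was 0.486 against 0.0839. The simulated spread of the shared pools thus accounts for 0.0839 of the covariance and leaves 0.402. Part of the excess of shared calls over independent lists may come from the shared controls. The overlap was 55 with lot as a block, and 50, 24, 14, 36 and 197 without wild-type pools 40, 41 and 42 and adjacent glands 49 and 51.

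The last comparison asked whether the changes of the first tumors recurred in set B (n = 2). Against wild-type gland, 22 of 24 white adipocyte genes fell in set B and 1 rose (median -3.89), 24 of 34 fibroblast and matrix genes fell (-1.81), 14 of 19 endothelial genes fell (-2.01), 9 of 15 basal genes fell (-1.12) and 14 of 24 luminal genes rose and 1 fell (1.08). Adjusted over the list alone, 22, 26, 15 and 9 members of the first 4 lists fell, 1 adipocyte gene and 1 basal gene rose, and 16 luminal genes rose and 1 fell. These lists were called (adjusted p = 8.09e-21, 2.02e-12, 2.76e-08, 0.00123 and 6.78e-06); with an estimated correlation the values were adjusted p = 0.0178, 0.151, 0.151, 0.151 and 0.187. The ErbB list had 7 rising members, also when adjusted over the list alone (median 1.09, adjusted p = 0.00141, and adjusted p = 0.29 with an estimated correlation), and 18 of 24 skeletal muscle genes fell (19 adjusted over the list alone; median -3.25, adjusted p = 8.84e-09, and adjusted p = 0.313 with an estimated correlation).

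limma called 1998 probe sets between set B and wild-type gland, 967 higher and 1031 lower. Of the 2574 probe sets called in the first tumors 1626 (63.2%) were called in the same direction in set B and 98.6% had the same sign. In simulated groups without any change, set against the same pools, the 2574 and 1998 probe sets with the smallest p were taken. They shared a mean of 851 in the same direction (at most 899), and 80.1% of the 2574 had the same sign. These lists too were chosen on noise alone, so 851 is not the overlap expected from shared controls in these data. Independent lists would share 152 higher and 145 lower. The covariance of the fold changes was 1.26 against 0.0837 simulated. With no array in common, the tumor change against adjacent gland and the set B change against wild-type gland correlated across probe sets with r = 0.823, and 99.3% of the 1239 probe sets called in the former had the same sign in the latter, against 75.1% of all 8616. Amy1 did not recur in both set B tumors: it was at the floor in tumor 81 but at 26070 in tumor 80, against 8750 to 12480 in the wild-type pools. Between set B and the first tumors limma called 0 probe sets, with 932 at an unadjusted p under 0.05 and a smallest adjusted p of 0.338. camera called 2 lists between the tumor sets, without any member called alone: ribosomal proteins were lower in set B (median of 23 genes -0.51, adjusted p = 1.35e-07, and adjusted p = 0.908 with an estimated correlation), as were cell cycle genes (median of 43 genes -0.33, adjusted p = 0.00489, and adjusted p = 0.908 with an estimated correlation). Adjusted over the list alone, 6 ribosomal and no cell cycle genes fell. The 5 genes with the smallest p were Sema4b, Traf4, Mob2, Pa2g4 and Tubb3; the first 4 had log2 differences of -1.41, -1.03, -3.19 and 1.22, and Tubb3 was 2.01-fold lower, none of them called. The 3' to 5' ratios of Gapdh (-0.28 and -0.50) and actin (0.21 and 0.14) lay below each wild-type pool (0.11 to 1.48 and 0.90 to 1.51) in both set B tumors, so RNA integrity and group are not separated there either. Each tumor set had lots of its own, so lot and set cannot be told apart here. Without set B tumor 80 or 81, 1138 or 1053 probe sets were called against wild-type gland and 1011 or 959 recurred.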

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

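The tests of tumor cells, of more epithelium and of a lower share of epithelium, and the fits within a lot, were chosen only after the results were seen, and the bound of the RNA quality test was raised after its value was seen.

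Each count of calls was set beside the counts from other splits of the same arrays into groups of the same sizes. For tumors against wild-type gland, 1 of 56 splits, the real one, called as many probe sets (2574, highest other 6), so chance can be excluded, but 7 of 56 called as many lists (15, highest other 17), so for the number of lists it cannot. For tumors against adjacent gland, 100 splits drawn from 126 were used, the real one included. Only the real one called as many probe sets (1239, highest other 259, the split that follows lot 2001815) and as many lists (20, highest other 18). By this share chance can be excluded for both, but for the lists only narrowly, since another split called 18 and not all 126 were drawn. With lot as a block, 10 of these 20 lists lost their call. For adjacent against wild-type gland, 1 of 35 splits, the real one, called as many probe sets (101), the smallest share that 35 splits can give. Adjacent glands 23, 25 and 49 set against the other 4 arrays called 97, and the real count was 14 without pool 42. By this share chance is unlikely for the probe sets, but with counts this close it is not excluded. There 15 of 35 splits called as many lists (9, highest other 12), so chance cannot be excluded for the number of lists; the split that follows lot 2004907 called 10, and 4 of the 9 lists kept their call with lot as a block.

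The 101 calls between adjacent and wild-type gland could come from array lots or RNA quality as well as from the tissue. The lots are argued against as the whole cause: of 184 probe sets called between adjacent glands 23 and 25 and pools 41 and 42, 76.1% had the same direction within lot 2004907, against 53.1% of all probe sets, and of 34 called between glands 49 and 51 and pool 40 in a fit that also took its spread from the tumors (a fit of these 3 arrays alone called 0), 97.1% had the same direction in the other arrays. RNA quality stays open, since only 1 of 4 adjacent arrays lay within the wild-type range of the 3' to 5' ratio for each control gene (log2 ratios of -0.27 to 0.27 against 0.11 to 1.48 for Gapdh, and 0.38 to 1.52 against 0.90 to 1.51 for actin). The bound set beforehand counted any overlap against RNA quality and was met, but it was too weak, because an overlap by 1 of 4 arrays leaves the other 3 outside the range. The transgene, the age of the mice and their strain, which differed between pools, also stay open and were not tested.

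The 62 rises in adjacent gland could reflect tumor cells in these samples, more epithelium, or a change within the gland. The risers below are not these calls but the 62 probe sets with the smallest p that were higher in the adjacent glands used to choose them. For the tumor share, risers also had to be at least 2-fold higher in tumors than in wild-type gland over all arrays. That choice therefore did not rest on the named glands alone. The test of more epithelium used risers without this condition. Risers chosen on glands 23 and 25 implied a tumor share of 0.249 in glands 49 and 51 (95% interval 0.161 to 0.311), against 0.287 (0.249 to 0.325) for 176 probe sets at least 4-fold higher in tumors, but those chosen on glands 49 and 51 implied 0.429 (0.326 to 0.515) in the others, against 0.248 (0.225 to 0.270), so tumor cells stay open. More epithelium also stays open: on arrays not used to choose them, the lower quartile of the risers was 0.158 and the luminal median 0.50, and the other way round 0.571 and 0.640. A change within the cells of the gland was not tested.

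Single arrays far from the others of their group were found for 14 of 182 combinations of gene and group, where chance flags about 1 in 20 groups. The values in parentheses below are the gap to the nearest array over the range of the group. For genes this ratio was taken on log2 values, while the intensities beside it are linear. Among tumors, Retn stood at 437 in tumor 52 and at the floor in the others (1), as did Ryr1 at 121 in tumor 24 (1), Cldn5 at 104 in tumor 26 (1) and Cnn1 at 102 in tumor 22 (1), all 3 close to the floor; these 4 values are 1 because the other arrays were set to the floor, so the chance rate does not apply to them. Vwf stood at 174 in tumor 50 against at most 102 (0.986), Ogn at 179 in tumor 50 against at most 119 (0.723), Csn3 at 180800 in tumor 52 against at most 90520 (0.793), Mrc1 at 202 in tumor 52 against at least 431 (0.74) and Scrg1 at 1137 in tumor 24 against at least 4309 (0.756). Among adjacent glands, Car8 stood at 523 and Dok1 at 1784 in gland 49, against at most 380 and 986 (0.874 and 0.941), Slc2a1 at 2242 in gland 51 against at most 889 (0.89), Ces1d at 4790 in gland 25 against at least 9126 (0.882) and Igha at 4513 in gland 23 against at least 15030 (0.851). Tumor 24 lay at -28.9 on the first principal component against -48.3 to -43.6 for the other 4 of its group (0.758), and adjacent gland 25 had a median correlation of 0.812 with its group against 0.886 to 0.899 (0.842). The 18S ribosomal RNA control, which entered no comparison, had a mean of 2312 ± 1539 (SD) in the 5 tumors, each above the highest wild-type pool at 400; it ran from 1002 to 4551 in lot 2001815 and from 282 to 1038 in the other lots.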

How the results depend on the processing

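Fits within a lot were added after the data were seen; all other alternatives were chosen before. The directions of named genes held under most settings, while the number of calls between adjacent and wild-type gland depended on several. Of the 301 named results, 289 kept direction and side of the threshold with quantile normalization, 289 with median scaling, 253 without a filter and 291 with lot as a random block (correlation within lots 0.151); with lot as a fixed block 159 of 296 did, 131 kept the direction but lost the call, and 6 changed direction. The cause of the changes below was not tested, except that a fixed block and fits within a lot leave fewer arrays per difference, and in simulations the block recovered 13% of 4-fold changes between tumors and wild-type gland.

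Tumors against wild-type gland gave 2574 calls, but 360 with lot as a fixed block and 921 with 2 lots also taken as one. On that last reading, 230 of 296 named results kept direction and side of the threshold, 65 lost the call and 1 changed direction. Statements on single genes and lists with lot as a block use the lots as numbered. Tumors against adjacent gland gave 1239, but 597 with lot as a fixed block and 209 within lot 2001815. Adjacent against wild-type gland gave 101, but 53 without a filter, 181 with array weights, 56 with lot as a fixed block, 26 with 2 lots taken as one, 28 with only the 2 groups compared and 0 by limma within lot 2004907 (523 at an unadjusted p under 0.05), and its overlap with tumor calls went from 101 to 52, 181, 55, 26 and 28 under the first 5 of these. Median scaling gave 35 higher and 44 lower calls there, and a floor at the 40th percentile 45 and 80, against 62 and 39. Set B against the first tumors gave 0 calls, but 2 with a floor at the 40th percentile and 1 without a filter. Of 44 list calls, 32 held with fry, which called 37 lists, and 5 with an estimated correlation, and with lot as a fixed block 26 lists were called, 22 of them among the 44. The median log2 change of all probe sets between tumors and wild-type gland was 0.16, or 0.12 with quantile normalization and 0.10 with median scaling.

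With lot as a fixed block, Ucp1 and Ttk turned to 0.0246 and -0.101 in tumors against wild-type gland, and Ucp1, Cox8b, Ctsb and Slc4a1, none of them called, to 0.0246, 0.191, 0.0397 and -0.036 in adjacent against wild-type gland, as they did within lot 2004907. The first of these Ucp1 values says nothing about tumors, since all tumors and both adjacent glands of their lot were at the floor. Ctsb turned to 0.0252 with 2 lots taken as one, and Slc4a1 ranged from -3.67e-04 (without gland 25) to 0.57 when 1 array was left out. The direction of the list test turned with the block for lipid synthesis in tumors (median -0.155) and adjacent gland (-0.0736), cell cycle in adjacent gland (-0.0936) and oxidative phosphorylation in tumors against adjacent gland (0.0162). Leaving out each array in turn gave 1774 to 2512 calls for tumors and 14 to 200 for adjacent gland against wild-type gland (50, 24 and 14 without pools 40, 41 and 42, and 36 and 200 without glands 49 and 51), 878 to 1379 for tumors against adjacent gland, 1053 to 1664 for set B against wild-type gland (1138 and 1053 without tumors 80 and 81) and 0 to 3 against the first tumors, 959 to 1683 repeated calls in set B (1011 and 959 without tumors 80 and 81), 14 to 197 shared calls and 37 to 44 list calls. Where this left 1 array in a group, that array was assumed to vary like the other groups. No paired analysis was possible because the labels do not say which adjacent gland surrounds which tumor, and lot as a fixed block cannot be fitted for set B, whose lot holds no other group. Signals near the floor (2.32% of tested values) give only lower bounds of a fold.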

Other observations

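Fits within a lot, the test of a lower share of epithelium and the choice of Xist were made only after the results were seen. Several gene lists fixed beforehand were not called in tumors against wild-type gland but held members that moved in both directions. Of 12 B and plasma cell genes 2 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.371): the immunoglobulin genes Igha and Jchain fell by 4.62 ± 0.41 and 3.88 ± 0.34 on the log2 scale, while Pax5 rose by 2.23 ± 0.48. Of 20 genes of hypoxia and glycolysis 4 rose and 4 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.852), with the aldolase gene Aldoc up by 4.30 ± 0.53, the glucose transporter gene Slc2a1 up by 2.22 ± 0.35 and the hexokinase gene Hk2 down by 2.51 ± 0.31. Of 30 genes of the TGF-beta and activin pathway 8 rose and 8 fell (10 and 8 adjusted over the list alone; list adjusted p = 0.587), with the inhibitors of differentiation Id1 and Id3 down by 2.57 ± 0.35 and 2.59 ± 0.27. Of 20 immediate early genes 6 rose and 3 fell, also when adjusted over the list alone (list adjusted p = 0.761), with Ier3 up by 4.11 ± 0.42 and the transcription factor gene Klf4 down by 2.47 ± 0.32. Of 13 genes of acute phase and complement 3 rose and 6 fell, also when adjusted over the list alone (list adjusted p = 0.133), with Lcn2, which encodes a carrier of siderophores, up by 2.78 ± 0.30 and the plasma protein gene Orm1 with a log2 change of at least -5.81 ± 0.37. With lot as a block, Igha, Jchain and Pax5 had log2 differences of -3.08, -2.88 and 2.22, Aldoc, Slc2a1 and Hk2 of 5.46, 3.20 and -1.92, Id1, Id3, Ier3 and Klf4 of -1.82, -2.47, 4.32 and -2.56, and Lcn2 and Orm1 of 3.00 and at least -4.74; Igha, Pax5, Hk2 and Id1 were not called with it. The remaining lists had list adjusted p of 0.861 (T cell, 8 genes, 1 fell), 0.323 (macrophage, 24 genes, 3 rose and 4 fell), 0.852 (neutrophil, 7 genes, 1 rose and 1 fell), 0.208 (MHC class II, 9 genes, 1 rose and 4 fell), 0.888 (Wnt pathway, 22 genes, 4 rose and 4 fell), 0.108 (apoptosis and p53 targets, 19 genes, 6 rose and 1 fell), 0.371 (peripheral nerve, 8 genes, 2 rose and 1 fell), 0.0926 (blood cell globins, 5 genes, 1 rose and 3 fell) and 0.133 (ribosomal proteins, 23 genes, 2 rose). These counts were the same adjusted over the list alone, except that 7 apoptosis genes, 3 nerve genes and 1 ribosomal gene rose.

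Tumors differed from adjacent gland in 6 further lists, all downward. Of 5 blood cell genes 3 fell (4 adjusted over the list alone), with the alpha-globin gene Hba-a1 down by 1.80 ± 0.29; the median was -1.61, or -1.79 within lot 2001815, with adjusted p = 0.00322 and adjusted p = 0.0941 with an estimated correlation. Of 13 genes of acute phase and complement 6 fell and 3 rose (7 and 3 adjusted over the list alone), with the haptoglobin gene Hp down by 3.14 ± 0.40; the median was -0.99, or -1.19 within the lot, with adjusted p = 0.0145 and adjusted p = 0.19 with an estimated correlation. Of 7 brown adipocyte genes 4 fell (5 adjusted over the list alone), of 17 basement membrane genes 8 fell (8 fell and 4 rose) and of 18 proteases and inhibitors 4 fell (6), with adjusted p = 5.84e-04, 0.0145 and 0.00386, and adjusted p = 0.19, 0.39 and 0.19 with an estimated correlation. Their medians were -2.01, -0.73 and -0.39, or -1.12, -0.31 and -0.24 within the lot. The brown adipocyte genes Ucp1 (not called here) and Cox8b stood at the floor and at 3124 and 2350 in glands 23 and 25, and at 8265 and 10160 and at 5901 and 9392 in glands 49 and 51. Of 32 oxidative phosphorylation genes 3 fell, also when adjusted over the list alone (median -0.17, or 0.02 within the lot; adjusted p = 0.0145, and adjusted p = 0.526 with an estimated correlation). Between adjacent and wild-type gland 22 lists were not called; with lot as a block, 3 of them were, namely B and plasma cell, macrophage and interferon response, whose medians were 0.53, 0.22 and 0.28 without the block and 0.70, 0.46 and 0.52 with it; the blocked test used the preset correlation, and without the block these lists had adjusted p = 0.757, 0.796 and 0.796 with an estimated correlation. Set B against wild-type gland also called the lists of brown adipocyte, lipid synthesis, basement membrane and oxidative phosphorylation downward and of cell cycle and protein folding upward, with adjusted p of 0.00119, 0.0261, 0.00296, 3.98e-06, 0.0293 and 0.00384, and adjusted p = 0.29, 0.452, 0.29, 0.29, 0.713 and 0.207 with an estimated correlation. In the first 4 of these lists 4, 7, 6 and 16 members fell and 1 basement membrane gene rose, and in the last 2 lists 2 and 9 rose; adjusted over the list alone, 7, 8, 10 and 18 fell, 2 lipid synthesis and 3 basement membrane genes rose, and 0 and 9 rose.

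Xist, the RNA that coats the inactive X chromosome, ran from 5000 to 11200 in the 5 tumors, from 2167 to 2447 in set B, from 381 to 7055 in the 4 adjacent glands and from 527 to 973 in the 3 wild-type pools. It was higher in tumors than in wild-type gland by 3.40 ± 0.61 on the log2 scale (adjusted p = 5.47e-04; 5.12 with lot as a block). The difference between adjacent and wild-type gland was 1.23 ± 0.63 (adjusted p = 0.382; 1.95 within lot 2004907), and that between set B and wild-type gland 1.72 ± 0.76 (adjusted p = 0.117), neither of them called. Between tumors and adjacent gland it was 2.17 ± 0.56 (adjusted p = 0.0145; 3.16 within lot 2001815).

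Luminal genes moved in opposite directions in tumors: Epcam, Ehf and Spint1 rose, while Krt19 fell 55.1-fold, Foxa1 19.6-fold and Cited1 8.16-fold. The median log2 change of the 24 luminal genes was 1.22, with a bootstrap 95% interval over genes, taken as independent, of 0.85 to 1.65. This argues against a lower share of all epithelium in the tumor samples as the cause of these falls. Foxa1 and Cited1 are not among the 24 genes, and a lower share of hormone-sensing cells alone was not tested. The hormone-sensing list was not called in tumors against wild-type gland (adjusted p = 0.133), and its member Socs2 rose 14.9-fold. No biological explanation of these opposite changes was tested.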
